A study of Mus musculus with 2 samples.

How the data were processed

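MicroRNAs (miRNAs) were profiled by array in cultured mouse pulmonary arterial smooth muscle cells, the contractile cells of the wall of the lung's arteries. There were 2 samples, 1 of wild-type cells and 1 of cells deficient in NOX1, a catalytic subunit of the superoxide-producing NADPH oxidases. Per the labels' protocols, each sample came from cells of 3 male mice on the C57BL/6 background. Cells at passage 3 were plated at 150000 per well in 12-well plates and kept for 24 hours in DMEM/F-12 with 10% fetal bovine serum. Total RNA was prepared with the miRNeasy mini kit and labelled with the dye Hy5 using the miRCURY kit, per the labels' protocols. Whether cells or RNA of the 3 mice were pooled is not given in the sources used here, and each genotype is represented by 1 array.

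The deposited table holds 1 intensity per feature and sample, on a linear scale in arbitrary units, for 739 features. That the scale is linear was read from the values, which are all above 0, carry 2 decimals and reach 51870. The scanner, background correction, normalization between arrays and detection limit are not given in the sources used here. The table lists 193 values as null on the wild-type array and 214 on the NOX1-deficient array. The lowest listed values were 0.96 and 0.93. A null could be a value under a detection limit or a rejected spot, and the table does not say which. Spots per feature and their spread were not used here, so the error of a single intensity is unknown. The number of arrays limits the precision throughout.

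Features carry miRBase mature-sequence accessions only. The sources used here held nothing that pairs these with miRNA names, so no feature was given a name. A reference gene table was searched as well and held none of the 739. In addition, 5 features carry more than 1 accession. The 21 lists of miRNAs fixed beforehand covered smooth muscle, pulmonary hypertension, hypoxia and redox, seed families, genomic clusters and fragments of longer RNAs. They also covered markers of endothelial, blood, epithelial, striated muscle, neuronal and mesenchymal cells. All are written by miRNA name, and none of them was evaluated. For the same reason the text prints 2 features per direction, fewer than the rule called for.

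The log2 difference, NOX1-deficient minus wild-type, was computed from the deposited intensities as they stand, with no pseudocount, for features with a value on both arrays. The features counted were those whose mean log2 intensity over both arrays was at or above the median, since small intensities give large ratios. The plan set this filter on named mouse miRNAs. With no names, all 472 features measured on both arrays were used, and whether each is a mouse miRNA was not checked. The fixed rule chose the 12 largest positive and the 12 largest negative differences among these, and a difference of 1 on the log2 scale (2-fold) as the threshold. With 1 array per genotype no test of the genotypes was made and no p-value is given. Correlations are across features, which are not independent replicates. The position of a group of features was described by the percentile of its median among 10000 random groups of the same size drawn from the same 10 brightness classes.

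The count was tested on simulated data with the measured spread per brightness class and 200 features changed. Among the brighter features, the 2-fold threshold counted 34 of 34 features planted at 4-fold, 36 of 37 planted at 2.5-fold, 1 of 36 planted at 1.5-fold and 0 of 129 left unchanged. The simulated noise was normal and took its spread from the measured differences between the 2 arrays. These counts check the procedure and do not measure the error of the arrays, which is unknown without replicates. For groups of 14 bright features, 4 of 100 unshifted groups and 100 of 100 groups shifted by -0.3 on the log2 scale fell below percentile 2.5. These groups were random features with independent noise. The planted shift was larger than the median of -0.10 reported below for a block of 14 features. The simulation therefore gives neither the power nor the error rate for that block.

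Alternatives fixed before the data were examined were median centring, quantile normalization, a loess curve of the difference on brightness (span 0.4), no brightness filter, the brightest quartile alone, log2(intensity + 50) and a 1.5-fold threshold. Setting nulls to the array's lowest listed value was added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.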

Results

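The miRNAs of pulmonary arterial smooth muscle cells were measured on 1 array of wild-type cells and 1 array of NOX1-deficient cells. Of 739 features, 546 had an intensity in wild-type cells and 525 in NOX1-deficient cells. On both arrays a few features held most of the summed intensity, which is no measure of abundance because probes differ in affinity and labelling. The brightest feature, the same on both arrays, held 45.2% of the summed intensity in wild-type cells (51870 units) and 45.5% in NOX1-deficient cells (51059 units). The 10 brightest held 79.0% and 78.4%, and all 10 were shared, as were all of the 20 brightest. At the other end, 185 wild-type and 179 NOX1-deficient intensities were below 2 units, within reach of the lowest listed values of 0.96 and 0.93. The median listed intensity was 3.31 units in wild-type and 3.42 units in NOX1-deficient cells, and the summed intensities were 114672 and 112103 units. The array carries miRNA features, so loss of NOX1 itself was not checked here.

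The comparison asked which miRNAs differ in abundance between smooth muscle cells with and without NOX1. Among the 236 brighter features, with mean intensities from 4.44 units up, 0 were at least 2-fold higher and 0 at least 2-fold lower in NOX1-deficient cells. At a threshold of 1.5-fold, 3 were higher and 4 were lower. The differences centred on 0.01 on the log2 scale (SD across features 0.24), with 122 features above 0 and 114 below. In 197 of the 236 features (83.5%) the genotypes lay within 1.25-fold of each other. Across these features the log2 intensities of the 2 arrays correlated with Pearson r = 0.996 and Spearman rho = 0.981. With 1 array per genotype, none of these differences has a replicate check, and no feature can be called changed or unchanged.

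The largest differences among the brighter features were found in dim members of that set. MIMAT0003151 read 5.01 units in wild-type and 8.60 units in NOX1-deficient cells, which is 1.72-fold higher (log2 difference 0.78). MIMAT0000671 read 4.60 and 7.21 units, 1.57-fold higher (log2 difference 0.65). In the other direction, MIMAT0000597 read 6.29 units in wild-type and 3.32 units in NOX1-deficient cells, 1.89-fold lower (log2 difference -0.92). MIMAT0004530 read 6.29 and 4.03 units, 1.56-fold lower (log2 difference -0.64). These 4 features ranked 182, 193, 231 and 212 by brightness among the 472 features measured on both arrays. The 12 largest positive differences ran from 0.39 to 0.78 and the 12 largest negative ones from -0.39 to -0.92. Mean intensity was below 10 units for 6 of the 12 higher and 9 of the 12 lower features. It was above 100 units for 3 of the higher features and for 0 of the lower ones.

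**Figure D1:**
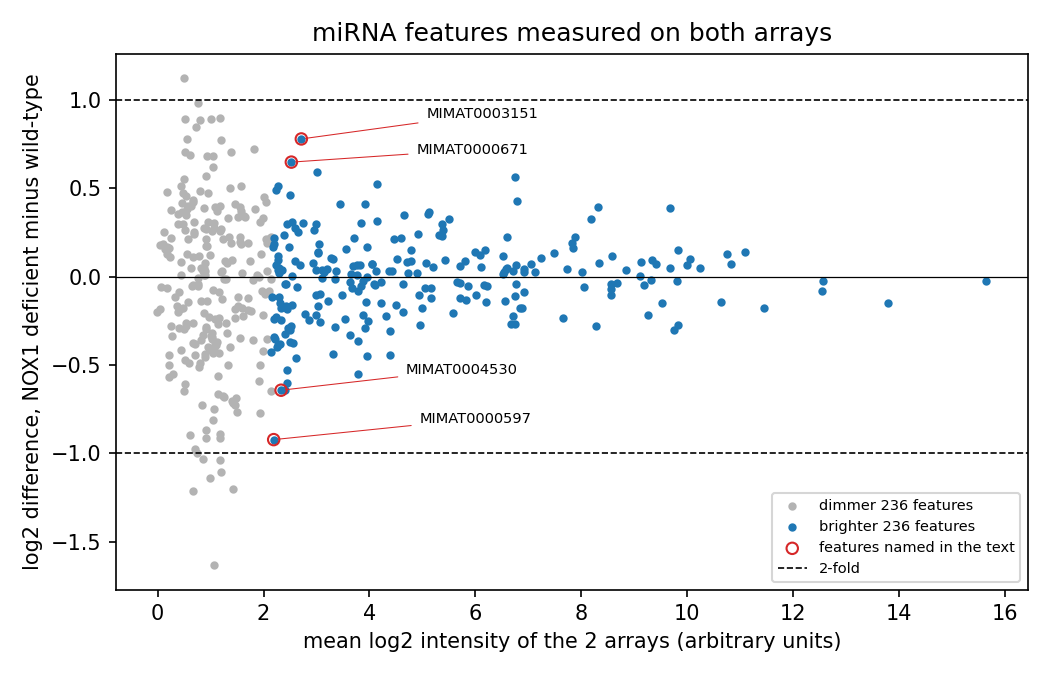
Each point is 1 of the 472 features measured on both arrays, with the mean log2 intensity (arbitrary units) on the x axis and the log2 difference, NOX1-deficient minus wild-type, on the y axis; dashed lines mark 2-fold and red circles the 4 features named in the text. The spread is narrower among the brighter features, and the 9 points at or past 2-fold all lie among the dimmer 236 features.

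Among the 118 brightest features, with mean intensities of at least 19.9 units, the differences had an SD of 0.18 on the log2 scale and 0 features reached 1.5-fold in either direction. The largest increase there was from 88.6 units in wild-type to 130.8 units in NOX1-deficient cells (1.48-fold). It was followed by features that read 95.9 and 129 units (1.35-fold), 279 and 367 units (1.31-fold), and 715 and 935 units (1.31-fold). The largest decrease was from 24.6 to 18.1 units, or 1.36-fold. The next decreases in order were from 23.3 to 18.8 units and from 964 to 784 units, each a ratio of 0.81. The 4 brightest features of all had NOX1-deficient over wild-type ratios of 0.98, 0.90, 0.98 and 0.94. On the log2 scale these are -0.02, -0.15, -0.02 and -0.08. Subtracting the difference of -0.10 between the array medians would turn all but the 2nd positive, so those directions depend on the scaling. The differences over the 472 features measured on both arrays already had a median of 0.004, however. That subtraction would therefore move them off 0.

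The spread differed with brightness. From the dimmest to the brightest of 4 groups of 118 features, the SD of the log2 difference was 0.45, 0.47, 0.29 and 0.18. Of the 236 dimmer features, 1 was at least 2-fold higher and 8 at least 2-fold lower in NOX1-deficient cells. The most extreme of these read 3.69 units in wild-type and 1.19 units in NOX1-deficient cells.

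Some features were listed on 1 array only. There were 74 with an intensity in wild-type cells alone and 53 in NOX1-deficient cells alone, while 140 had none on either array. Intensities listed on 1 array were low, with a median of 1.29 units in wild-type (highest 2.28) and 1.24 units in NOX1-deficient cells (highest 2.93). If a null stands for a value below the lowest one listed, at least 4 features of each kind would differ by at least 2-fold.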

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

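The counts of 0 features at least 2-fold higher and 0 at least 2-fold lower were also found under median centring, quantile normalization and the loess curve. The brightest quartile and log2(intensity + 50) gave 0 by construction, since the first is a subset of the counted features and the second shrinks ratios. Without the brightness filter they became 1 higher and 8 lower, and at 1.5-fold they became 3 and 4. With nulls at the lowest listed value and no filter, a setting chosen after seeing the data, they became 5 and 12. The SD of the differences, 0.24, was 0.37 without the filter, 0.18 in the brightest quartile and 0.0876 with log2(intensity + 50). The median difference, 0.01, became 0.11 under median centring. That setting subtracted the difference of -0.10 between the medians of the 2 arrays over the 472 features measured on both. Those medians were 4.55 units in wild-type and 4.26 units in NOX1-deficient cells. The differences over the same 472 features had a median of 0.004, so median centring moved them off 0. The 4 named features had the same sign in all 16 recomputed values, with sizes from 0.06 to 0.88 on the log2 scale. The lowest sizes came from log2(intensity + 50), which cannot turn a sign, and median centring moved each value by 0.10, too little to turn one. No paired analysis was possible because each genotype has 1 array, and leaving out a replicate was not possible for the same reason. The alternatives on probes per miRNA and on arms in a list were not run, since features are unnamed and each has 1 value. No background values were used here, so how far signal over background limits the dimmer features is unknown.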

Other observations

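A small set of features with neighbouring accession numbers held most of the summed intensity on both arrays, which does not rank miRNAs by abundance because probes differ in affinity and labelling. The 17 features numbered from 11000 to below 12000 held 64.6% of the summed intensity in wild-type cells and 63.4% in NOX1-deficient cells. The 204 features numbered below 1000 held 16.5% and 18.1%. The accession numbers name no miRNA here, so what these features detect was not determined.

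The blocks of accession numbers were compared after the intensities had been seen; the percentile test of the block was written down before it was run, and the checks with other scalings, with 20 brightness classes and above 100 units were chosen after. Of the 14 brighter features numbered from 11000 to below 12000, 11 were lower in NOX1-deficient cells, with a median log2 difference of -0.10. Of the 114 brighter features numbered below 1000, 76 were higher, with a median of 0.06. Median centring adds 0.10 to every difference, about the size of the 11000 block's shift. It took that block's median to -0.01 and that of the block below 1000 to 0.16. Under that scaling the 11000 block is thus lower only relative to other features. The differences over all 472 features already had a median of 0.004 before that centring. Quantile normalization gave medians of -0.03 and 0.04 for the 2 blocks, and the loess curve gave -0.10 and 0.06. The median of the 11000 block lay at percentile 0.17 of 10000 random groups matched on brightness. Those groups had a median of 0.03 and a central 95% from -0.05 to 0.09. This does not decide whether brightness-dependent scaling between the arrays lies behind the shift. The block was picked after the intensities had been seen. The random groups were drawn from features that include the block itself and the block below 1000. The percentile was 0.21 after the loess curve and 0.29 with 20 brightness classes. After quantile normalization the percentile was 0.71, but the 11000 block's median was -0.03 against 0 for the random groups, a much smaller gap. The gap to the random groups was thus smaller under quantile normalization than with the deposited values or after the loess curve. Quantile normalization gives a difference of 0 to any feature with the same rank on both arrays, so the smaller gap does not by itself measure the shift. Among features above 100 units, 11 of 13 in the block and 17 of 48 outside it were lower. The features outside include many of the block below 1000, which was mostly higher, so this contrast does not single out the 11000 block. In all, 8 of the 10 blocks had enough members for a percentile. Of these, 2 fell outside the central 95% of random groups, the 11000 block and the block below 1000 at percentile 99.99. The 2 are not independent, because the random groups for each were drawn from features that include the other. Lower medians were not particular to the 11000 block. Blocks starting at 3000, 4000, 5000, 7000 and 9000 had medians of -0.09, -0.03, -0.15, -0.10 and -0.05. The block starting at 1000 had 0.01, and these blocks had percentiles from 4.22 to 50.61. Members of a block may share a source, and a group with a shared source moves together more readily than random features do. Scaling between the arrays, a difference in RNA preparation or labelling and an effect of the NOX1 genotype cannot be told apart, because there is 1 array per genotype.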
